A study of Homo sapiens with 3 samples.

How the data were processed

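RNA of 3 libraries of Caco-2 cells at day 21 of differentiation was sequenced; per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit and read as pairs on a HiSeq 2000. The submitters' processing notes name kallisto, with the version given as 42.5. The genome build, the annotation release and any use of strand are not given in the sources used here. Per the file headers, each table holds for 58526 gene symbols a length, an effective length, an estimated count, a TPM and a type. The deposited estimated counts (expected counts that need not be whole) carry depth, with totals of 33481101, 20843874 and 28196656 in replicates 2, 3 and 4. The deposited TPM values are scaled within each library by the authors to a fixed sum and corrected for transcript length, so they carry no depth. The type column names 1 transcript type per symbol: 10577 protein-coding genes carry another type in it.

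Gene class was therefore taken from the symbol in GENCODE 29, matched also through older symbols (35395 entries), then from RefSeq (273 entries), and for the other 22252 from the deposited type where it settles the class; 606 stayed unresolved and outside both classes. Of the lncRNA entries, 11698 were classed by the deposited type, and 17 detected lncRNA entries held counts equal to those of another entry. Symbols built from a clone accession were never matched by name. GENCODE 29 coordinates (GRCh38) are quoted for genes matched by symbol.

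A gene was detected at a TPM of at least 1 in all 3 libraries. Class and list levels were compared within each library as differences of medians of log2(TPM + 0.1), a scale that understates the difference of low genes, and tested with an exact two-sided sign-flip permutation over the 3 libraries, with Benjamini-Hochberg adjustment over the 10 lists set against the enterocyte list. The 24 gene lists, the 10 lncRNA pairs and the tests were fixed before the data were examined. A list's median was also placed among 10000 random lists of the same size, drawn from protein-coding genes, or from lncRNAs for lncRNA lists. A pair's ratio was formed where both genes had at least 3 estimated counts in each library.

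Spread between libraries was estimated with edgeR 4.0.16 from estimated counts rounded to whole numbers, with TMM scaling, filterByExpr and an intercept-only design; each gene's quasi-likelihood dispersion was tested against the trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tested on simulated counts for the 18078 genes, in which 1 library was shifted in 200 genes, the test recovered 81% of genes at a 4-fold and 98% at a 16-fold shift, with 7 false calls and 0 calls when no gene was shifted. That simulation gave every gene the dispersion of the trend; with shifts planted in 200 genes of the real counts, a test added after the data were seen, it recovered 0% at a 4-fold and 0% at a 16-fold shift, although 90% and 100% had an unadjusted p under 0.05. DESeq2 1.42.0 and limma 3.58.1 served as alternatives, in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Transcript GC content was that of the longest GENCODE 29 transcript of a gene, and the length and GC trend between libraries was fitted over 9780 protein-coding genes with a mean TPM of at least 5. On shuffled deviations with a planted slope of 0.1 and a shift of 0.5 in 200 genes, a slope of 0.0994 and a shift of 0.499 were found. A least-squares fit returns a planted slope by construction. The slope thus checked the calculation only, and not how well the trend describes these libraries.

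Genes were named by a rule fixed beforehand: in each list the 4 members with the highest and the 2 with the lowest mean TPM, any member of lists of 10 or fewer genes, of the transcription factor list, of the lncRNA lists and of the pairs, the 10 protein-coding genes and 10 lncRNAs with the highest mean TPM, and the 10 genes with the smallest p for variation among those with a mean TPM of at least 1. SI and the genes and groups that open the other observations were chosen after their values were seen. Some genes and pairs that the rule covers are not reported here.

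The alternatives were other TPM minimums, a minimum in 2 libraries, an estimated count of at least 10, other pseudocounts, no filter, CPM, rescaling to nuclear protein-coding genes, list means, other scalings and dispersion tools, and leaving out each replicate. Class from the type column alone, unresolved entries counted as lncRNA, lncRNAs of at least 200 bases and removal of the length and GC trend were added after seeing the data. Precision is limited by 3 libraries and, for low genes, by depth: 3 counts correspond to 0.0896, 0.144 and 0.106 CPM, and such limits cover counting error only.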

Results

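RNA from Caco-2 cells was measured by RNA sequencing after 21 days of differentiation. Caco-2 is an established human colon carcinoma line whose cells, once confluent, polarise and form a brush border like that of absorptive enterocytes. The 3 libraries made up 1 group and carried the replicate numbers 2, 3 and 4. The series set out to record which protein-coding and long non-coding RNA (lncRNA) genes these cells express, and no second group was compared with them. The estimated counts summed to 33481101 in the replicate 2 library, 20843874 in replicate 3 and 28196656 in replicate 4. Levels are given in TPM, a length-corrected share of each library's transcripts, as mean ± SD over the 3 libraries, and a gene was called detected at a TPM of at least 1 in all 3. An estimated count of 0 allowed up to 0.0896, 0.144 and 0.106 CPM (counts scaled to library total) in replicates 2, 3 and 4 (3 counts of the total, counting error only). The labels do not say that the libraries came from separate cultures, so p-values speak only of these samples, whose spread may be technical. With 3 libraries an exact two-sided sign-flip permutation test cannot give a p below 0.25. It gives 0.25 whenever the 3 differences share a sign, whatever their spread.

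The first question was how many genes of each class were expressed and how strongly. The most abundant nuclear transcript was AFP, the fetal serum protein alpha-fetoprotein, at 18046 ± 3759 TPM (n = 3), followed by the translation elongation factor EEF1A1 at 14336 ± 2784 TPM and the ribosomal protein gene RPS27 at 11749 ± 4305 TPM. The mitochondrial genes MT-CO1 and MT-CO3, subunits of cytochrome c oxidase, stood at 15170 ± 5467 and 14686 ± 1603 TPM. Among lncRNAs the highest were LRRC75A-AS1 (1862 ± 449.5 TPM), ZFAS1 (1760 ± 432.8 TPM) and GAS5 (1089 ± 351.6 TPM), all hosts of small nucleolar RNAs. They were followed by 3 entries of the CH507-513H4 clone at 663.6 ± 56.7 TPM each and by SNHG6 at 509.8 ± 156 TPM. The 3 clone entries held identical values in each library, so their copies cannot be told apart. EEF1A1 and RPS27 have many processed pseudogenes, which leaves the split of their reads uncertain. In the replicate 2 library the levels were 13897 TPM for AFP, 1344 for LRRC75A-AS1 and 683.4 for GAS5, below replicate 3 (21226, 2145 and 1303 TPM) and replicate 4 (19015, 2097 and 1282 TPM).

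Of 20049 protein-coding entries, 11954 (59.6%) were detected, and of 14520 lncRNA entries, 2099 (14.5%). Counted per library, 12402 ± 234 protein-coding and 2725 ± 203 lncRNA genes reached a TPM of 1. The median detected lncRNA stood at 3.18 ± 0.231 TPM and the median detected protein-coding gene at 16.1 ± 2.93 TPM, a log2 difference of -2.29 ± 0.15, or 4.88-fold lower. The lncRNA median was the lower in 3 of 3 libraries (exact sign-flip permutation p = 0.25, two-sided). The size of the difference depends on the measure: it was -4.02 with no filter on detection and -3.99 in CPM. A TPM of 10 in all libraries was reached by 7007 protein-coding (58.6%) and 226 lncRNA genes (10.8%), and a TPM of 100 by 859 and 18. The lncRNAs held 2.51 ± 0.0584% of all TPM, nuclear protein-coding genes 79.0 ± 3.82% and the mitochondrial genes 14.1 ± 3.48%. The 10 most abundant lncRNAs alone held 0.824 ± 0.155%. The mitochondrial share was 17.7% in replicate 2, 10.8% in replicate 3 and 13.8% in replicate 4. The protein-coding count rests mostly on names matched to a reference annotation, but 11698 of the 14520 lncRNA entries were classed by the deposited type column. That column names the type of 1 transcript per entry. With the class of every entry taken from it alone, 4549 protein-coding and 5697 lncRNA genes were detected and the log2 difference was -0.63.

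**Figure D1:**
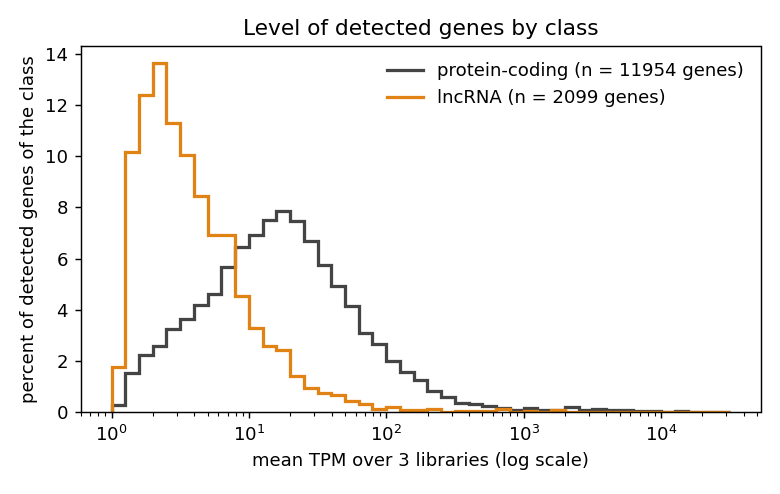
Distribution of the mean TPM over the 3 libraries (x axis, log scale) of detected protein-coding and lncRNA genes, as the percent of detected genes of each class (y axis). The lncRNA curve peaks at a lower TPM than the protein-coding curve, with per-library medians averaging 3.18 and 16.1 TPM.

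The next question was how far the cells expressed the genes of absorptive enterocytes. Of 27 enterocyte brush border genes, 23 were detected. The highest were FABP1, which binds fatty acids in the cytosol, at 1015 ± 35.8 TPM, the cadherin CDH17 at 296 ± 150 TPM, the microvillus protein villin (VIL1) at 286.2 ± 69.6 TPM and the peptidase DPP4 at 228.4 ± 81.4 TPM. Sucrase-isomaltase (SI), a disaccharidase of the brush border named here after its values were seen, stood at 169.8 ± 15.5 TPM. The lowest members were the sodium-coupled glucose transporter SLC5A1 (0.971 ± 0.144 TPM) and the peptidase MME (0.69 ± 0.294 TPM). The list median was 10.8 ± 3.18 TPM, with 14.4 TPM in replicate 2, 9.17 in replicate 3 and 8.67 in replicate 4, and stood above 89.4% of 10000 random lists of 27 protein-coding genes.

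Genes of fat absorption were high. APOA1, the main protein of high-density lipoprotein, reached 4498 ± 1316 TPM, APOC3 1215 ± 494.8 TPM, APOE 857.7 ± 62.8 TPM and APOM 253.7 ± 56.1 TPM. The sterol half-transporters ABCG5 (0.0495 ± 0.0217 TPM) and ABCG8 (0.0324 ± 0.0183 TPM) were the lowest of the 21 genes, of which 16 were detected, with a list median of 46.1 ± 2.76 TPM. Of 10 genes for bile acid and vitamin uptake in the ileum, 9 were detected: AMN, a part of the vitamin B12 receptor, stood at 43.98 ± 5.3 TPM, the thiamine transporter SLC19A3 at 40.85 ± 3.43 TPM and the basolateral bile acid exporter SLC51B at 39.47 ± 13.3 TPM. The apical bile acid transporter SLC10A2 was at 3.36 ± 2.67 TPM (6.43, 1.64 and 2.01 in replicates 2, 3 and 4) and the hormone FGF19 at 0.811 ± 0.201 TPM. All 13 cholesterol genes were detected, led by the mevalonate-pathway enzymes HMGCS1 (238.8 ± 13.2 TPM), IDI1 (212.9 ± 46.5 TPM) and FDPS (150 ± 11.5 TPM), with a list median of 59.9 ± 11.7 TPM.

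All 14 iron and metal genes were detected: the ferritin chains FTL (3712 ± 186 TPM) and FTH1 (2003 ± 29.7 TPM), the iron exporter ferroportin (SLC40A1, 350.4 ± 73.5 TPM) and the zinc transporter SLC39A5 (159.7 ± 6.98 TPM) were the highest, and CYBRD1 (4.60 ± 1.42 TPM) and MT1G (4.31 ± 1.83 TPM) the lowest. Of 22 drug transport and metabolism genes, 19 were detected. The glutathione transferases GSTA1 (1449 ± 729.6 TPM) and GSTA2 (1034 ± 407 TPM) led the list, ahead of the carboxylesterase CES1 (288.7 ± 62.3 TPM) and the uptake transporter SLCO2B1 (178.8 ± 60.8 TPM). CYP3A4, the main drug-oxidising enzyme of the intestine, stood at 0.219 ± 0.0193 TPM and CYP4F2 at 0.827 ± 0.0672 TPM. GSTA1 and GSTA2, the metallothioneins and the ferritin genes have near-identical copies, so their split between copies is uncertain. Of 18 junction genes, 17 were detected, with EPCAM at 848.5 ± 188 TPM, E-cadherin (CDH1) at 218.7 ± 182 TPM, CLDN1 at 194.7 ± 30.7 TPM and CLDN4 at 156.9 ± 36 TPM, while the pore-forming claudin CLDN2 was the lowest at 1.67 ± 0.595 TPM. CDH1 was at 428.5 TPM in replicate 2 against 106.4 and 121.1 in replicates 3 and 4, and the junction list median was at 76.4 TPM against 36.1 and 37.8. The list's median log2 deviation in replicate 2 was 0.395, and 0.125 once the length and GC trend between libraries was removed, a correction chosen after the data were seen.

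The cells also carried transcripts of secreted liver proteins. All 12 genes of this list were detected, with a median of 1400 ± 178 TPM, at a percentile of 100 among 10000 random lists of 12 protein-coding genes. Besides AFP, serum albumin (ALB) stood at 5327 ± 2375 TPM and the fibrinogen chains FGG and FGB at 3395 ± 777.1 and 1643 ± 128.9 TPM. Transferrin (TF) at 4.77 ± 2.38 TPM and AMBP at 3.37 ± 0.946 TPM were the lowest. ALB was at 2600 TPM in replicate 2, 6448 in replicate 3 and 6934 in replicate 4. The enterocyte list median was lower than the liver list median by a log2 difference of -7.04 ± 0.57, in 3 of 3 libraries (exact sign-flip permutation p = 0.25, adjusted p = 0.278 over 10 lists). This difference was smaller with list means, at -5.09, and in CPM, at -5.55.

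Against the other epithelial lineages, the enterocyte list stood higher in 3 of 3 libraries for 5 of 6 lists: the log2 difference of medians was 1.86 ± 0.25 against colonocyte, 4.26 ± 0.75 against goblet, 5.37 ± 0.15 against enteroendocrine, 5.15 ± 0.44 against tuft and 1.19 ± 0.023 against crypt stem cell and Wnt target genes. Each had an exact sign-flip permutation p = 0.25 (adjusted p = 0.278 over 10 lists). For the Paneth list it was 0.70 ± 1.34 (exact permutation p = 0.75), and -0.056 without replicate 2. With list means it was 1.77 and in CPM 3.06, with the enterocyte list higher in 3 of 3 libraries in both (exact permutation p = 0.25), so agreement between libraries for this list depends on the measure. Of 16 colonocyte genes, 10 were detected, led by the anion transporters SLC26A2 (96.96 ± 16.5 TPM) and SLC26A3 (78.82 ± 21.1 TPM). CA2, a carbonic anhydrase, was at 23.51 ± 4.6 TPM and CEACAM6, an adhesion molecule with close paralogs, at 17.67 ± 17.8 TPM (38.2, 6.97 and 7.83 in replicates 2, 3 and 4). MS4A12 had an estimated count of 0 in 3 of 3 libraries and the chloride channel BEST4 was at 0.041 ± 0.0364 TPM.

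Among 10 goblet cell genes, 4 were detected. The disulfide isomerase AGR2 stood at 1654 ± 33.5 TPM, the trefoil peptide TFF3 at 196.4 ± 64.1 TPM, ZG16 at 14.55 ± 5.37 TPM and REP15 at 1.46 ± 0.372 TPM. The gel-forming mucin MUC2 was at 0.194 ± 0.0983 TPM, and the secretory-lineage transcription factors SPDEF and ATOH1 were at 0.113 ± 0.0653 and 0.0533 ± 0.02 TPM. Of 7 Paneth cell genes, 6 were detected: the defensin DEFA5 at 16.25 ± 17.6 TPM (1.89, 35.8 and 11.05 in replicates 2, 3 and 4), lysozyme (LYZ) at 14.41 ± 2.99 TPM and the phospholipase PLA2G2A at 13.17 ± 1.74 TPM. Neurotensin (NTS, 1.91 ± 0.0677 TPM) was the only detected member of 12 enteroendocrine genes, and CHGB followed at 0.667 ± 0.256 TPM. SH2D6 (5.83 ± 1.94 TPM) and AVIL (2.97 ± 0.632 TPM) were the 2 detected tuft cell genes of 7, while the tuft cell regulator POU2F3 was at 0.158 ± 0.0908 TPM.

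All 18 proliferation genes were detected after 21 days of differentiation. The mitotic kinase CDK1 stood at 178.9 ± 38 TPM, the ubiquitin-conjugating enzyme UBE2C at 141.1 ± 72.6 TPM, the replication clamp PCNA at 113.5 ± 22.7 TPM and cyclin B1 (CCNB1) at 108.2 ± 47.7 TPM. MCM5 (17.77 ± 5.93 TPM) and MKI67 (15.81 ± 13.2 TPM) were the lowest. The list median was 74.9 TPM in replicate 2, 38.8 in replicate 3 and 37.9 in replicate 4, and MKI67 stood at 31.0, 9.07 and 7.39 TPM. The enterocyte list median was lower than that of the proliferation list by a log2 difference of -2.18 ± 0.16, in 3 of 3 libraries (exact sign-flip permutation p = 0.25, adjusted p = 0.278). Of 16 stem cell and Wnt target genes, 14 were detected, among them PROM1 (65.4 ± 23.9 TPM), MYC (21.43 ± 2.03 TPM), RNF43 (13.63 ± 4.1 TPM) and SP5 (11.54 ± 1.71 TPM), while NOTUM was at 1.95 ± 1.56 TPM (3.72, 1.34 and 0.785 in replicates 2, 3 and 4) and OLFM4 at 0.309 ± 0.287 TPM.

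Markers of cells outside the epithelium were mostly below the detection minimum. Of 12 immune genes, 2 were detected, the lysosomal protein gene CD68 (40.62 ± 12 TPM) and CD14 (2.51 ± 0.94 TPM), and TYROBP and FCGR3A had estimated counts of 0 in 3 of 3 libraries. Of 10 stromal and endothelial genes, 4 were detected: COL1A1 at 11.29 ± 6.84 TPM (19.2, 7.40 and 7.28 in replicates 2, 3 and 4), PDGFRB at 4.69 ± 1.06 TPM, PECAM1 at 3.03 ± 1.03 TPM and LUM at 2.64 ± 0.432 TPM. The stromal list median was 2.95 TPM in replicate 2, 0.659 in replicate 3 and 0.835 in replicate 4. Over its 6 genes with a mean TPM of at least 1, the median log2 deviation in replicate 2 was 0.714, and 0.117 once the length and GC trend between libraries was removed, a correction chosen after the data were seen. The enterocyte list median exceeded that of the immune list by 5.24 ± 0.29 and that of the stromal list by 3.04 ± 0.68 on the log2 scale, in 3 of 3 libraries each (exact sign-flip permutation p = 0.25, adjusted p = 0.278). Of 20 inflammation and antimicrobial genes, 5 were detected, among them the protease inhibitor PI3 at 113.2 ± 8.97 TPM, the mitochondrial superoxide dismutase SOD2 at 76.44 ± 13 TPM and the chemokine CCL20 at 4.31 ± 0.953 TPM. REG1A, which has the close copy REG1B, stood at 0.165, 7.19 and 2.81 TPM in replicates 2, 3 and 4 and so was not detected in all libraries. S100A8 (0.0552 ± 0.0956 TPM) and CXCL5 (0.00671 ± 0.0116 TPM) were the lowest.

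**Figure D2:**
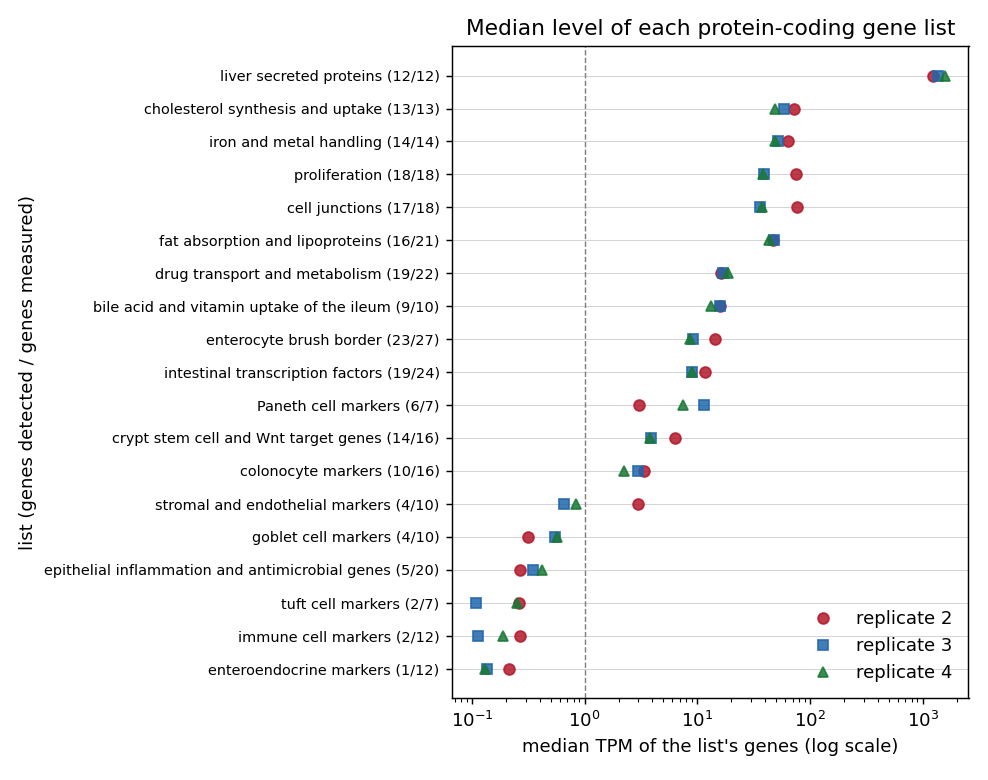
Median TPM (x axis, log scale) of each protein-coding gene list (y axis, with genes detected over genes measured) in the libraries of replicates 2, 3 and 4. The dashed line marks a TPM of 1. The liver secreted list lies highest at 1230 to 1580 TPM, and the proliferation list lies at 74.9 TPM in replicate 2 against 38.8 and 37.9 TPM in the others.

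**Figure D3:**
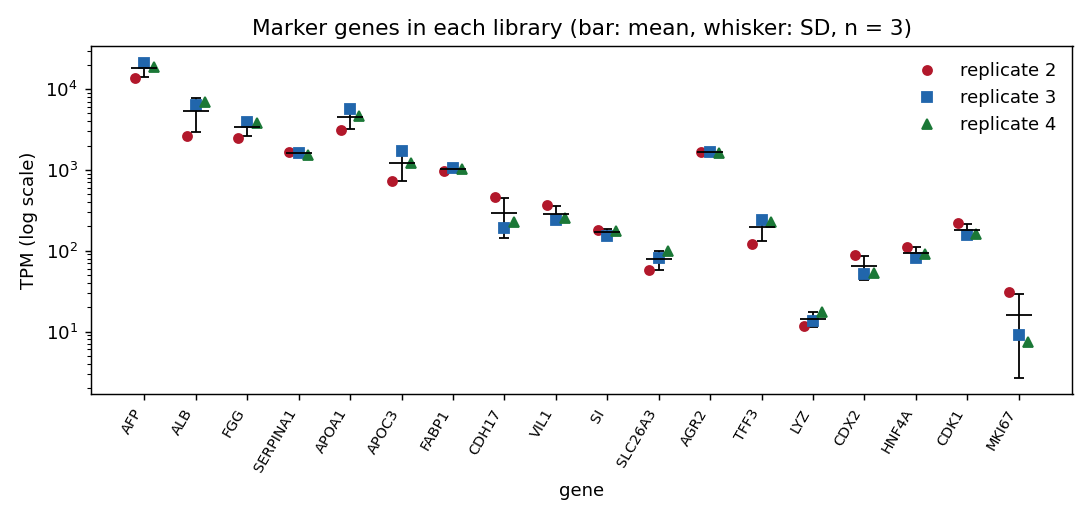
TPM (y axis, log scale) of marker genes (x axis) in each library, with the mean and SD of the 3 libraries. AFP lies highest at 13897 to 21226 TPM, and MKI67, at 7.39 to 31.0 TPM, has a wide spread between libraries.

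Of 24 intestinal transcription factors, 19 were detected, with a list median of 9.95 ± 1.58 TPM. FOXA1 and KLF5 stood highest at 109.4 ± 31.3 and 109.4 ± 50.2 TPM, followed by HNF4A, a nuclear receptor of hepatocytes and enterocytes, at 94.38 ± 16.6 TPM, ELF3 at 91.89 ± 26.2 TPM and the intestinal homeobox factor CDX2 at 64.62 ± 20.9 TPM. Its relative CDX1 was at 0.289 ± 0.184 TPM. GATA6 stood at 23.09 ± 10.6 TPM, GATA4 at 1.65 ± 0.467 TPM and GATA5 at 0.106 ± 0.0198 TPM. The drug-sensing receptor NR1I2 (0.882 ± 0.271 TPM) was not detected in all libraries, whereas PPARG stood at 33.82 ± 3.64 TPM.

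The lncRNAs tied to these factors were compared with their partner genes. GATA6-AS1 (22.43 ± 5.29 TPM; chromosome 18, 22164886 to 22169878 on the minus strand, GENCODE 29 on GRCh38) and GATA6 differed by less than the spread between libraries, with a log2 ratio of 0.022 ± 0.41 (exact sign-flip permutation p = 1), which was -2.11 in CPM, where transcript length is not corrected for, and -0.20 without replicate 3. HNF4A-AS1 (chromosome 20, 44372746 to 44395706, inside the span of HNF4A on the other strand) stood at 15.57 ± 9.86 TPM, with 4.22 TPM in replicate 2, 22.1 in replicate 3 and 20.4 in replicate 4. Its log2 ratio to HNF4A was -2.92 ± 1.59 (exact permutation p = 0.25), -4.74 in replicate 2 alone, -2.003 without replicate 2 and -6.42 in CPM.

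The ratio was also negative in 3 of 3 libraries (exact sign-flip permutation p = 0.25 each) for LINC00261 against FOXA2 (-1.46 ± 0.39) and CDKN2B-AS1 against CDKN2B (-2.20 ± 0.53), and positive for KCNQ1OT1 against KCNQ1 (3.23 ± 1.64). The last of these was 8.62 in CPM, 4.15 without replicate 3 and 2.56 without replicate 4, and that of CDKN2B-AS1 was -3.16 in CPM. For HOXA11-AS against HOXA11 it was 0.36 ± 0.45 (exact permutation p = 0.5). Several of these genes lay below the detection minimum. KCNQ1 had 9, 8 and 4 estimated counts in replicates 2, 3 and 4, so its ratio rests on few reads. CDKN2B-AS1 was at 0.689 ± 0.229 TPM, HOXA11-AS at 0.327 ± 0.136 TPM and HOXA11 at 0.245 ± 0.05 TPM. IFNG had an estimated count of 0 in 3 of 3 libraries while IFNG-AS1 was at 1.89, 0.517 and 0.574 TPM, and H19 was at 1.68, 0.0254 and 0.444 TPM while IGF2, its imprinted neighbour, was at 318, 152 and 145 TPM; no ratio was formed for these pairs. No strand information was used in these values as far as the sources used here state, so reads from the overlapping parts of a gene and its antisense partner cannot be told apart.

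**Figure D4:**
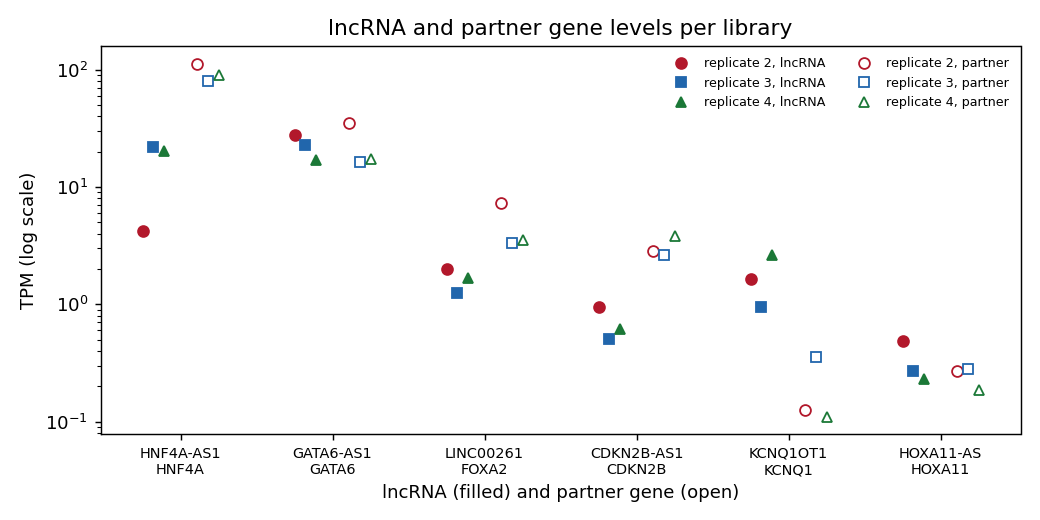
TPM (y axis, log scale) of 6 lncRNAs (filled) and their partner genes (open) in each library. HNF4A-AS1 lies below HNF4A in each library, and lies at 4.22 TPM in replicate 2 against 22.1 and 20.4 TPM in the others.

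Of the 6 lncRNAs listed as tied to a transcription factor, 5 were detected (list median 8.10 ± 4.5 TPM). The other was CDKN2B-AS1, whose partner CDKN2B is not among the listed transcription factors. All 18 abundant housekeeping lncRNAs were detected (148 ± 26.8 TPM). MALAT1 and NEAT1, which stay in the nucleus, stood at 145 ± 58.9 and 174.1 ± 35.3 TPM, NORAD, listed as LINC00657, at 216.3 ± 61 TPM and CYTOR, listed as LINC00152, at 10.25 ± 0.531 TPM. Of 13 genes listed as lncRNAs named in colorectal cancer, 10 were detected, 1 of them TINCR, which the reference annotation classes as protein-coding; CRNDE was highest at 69.5 ± 6.19 TPM, then HULC at 59.02 ± 27.7 TPM and UCA1 at 13.14 ± 2.54 TPM, while CCAT1 was at 3.11 ± 0.237 TPM and PCAT1 at 0.288 ± 0.113 TPM. Of 8 genes listed as lncRNAs of inflammation or immune cells, among them the microRNA gene MIR146A, DIO3OS was the only one detected (3.23 ± 0.978 TPM), and LINC01272 stood at 0.0739 ± 0.0463 TPM. Of 9 imprinted and developmental lncRNAs, HOTAIR (6.86 ± 3.11 TPM) and HOXB-AS3 (2.51 ± 0.681 TPM) were detected, and MEG3 was at 0.103 ± 0.0647 TPM.

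The last question was how far the replicates differed and whether lncRNAs varied more than protein-coding genes. The genes with the smallest p for varying more than genes of like count were mostly highest in replicate 2: the collagen gene COL1A2 stood at 5.40, 0.424 and 0.370 TPM in replicates 2, 3 and 4, the basement membrane proteoglycan HSPG2 at 32.0, 4.05 and 4.58, the membrane mucin MUC17 at 5.82, 0.326 and 0.662, CEACAM5 at 15.9, 2.79 and 2.22, and the endocytic receptor LRP1 at 51.1, 8.72 and 8.56 TPM. NID1 and NOTCH3 were likewise highest in replicate 2. The calcium-binding protein S100G (2.85, 50.9 and 21.7 TPM), DEFA5 and ZACN (0.327, 2.49 and 0.501 TPM) were highest in replicate 3. Of those highest in replicate 2, COL1A2, HSPG2, MUC17, NID1, NOTCH3 and LRP1 were 5864 to 14897 bases long, and CEACAM5 2874. S100G, DEFA5 and ZACN were 455, 449 and 2651 bases long. Most of these genes thus followed the direction of the length trend between libraries given below, which the test did not remove. The trend was far smaller than the differences of these genes. For transcripts over 8000 bases its median log2 deviation was 0.36 in replicate 2 and -0.31 in replicate 3. None of the genes named here passed the edgeR test of each gene's dispersion against the trend, with an adjusted p of 0.969 for COL1A2. Of 18078 genes tested, 0 passed, 811 had an unadjusted p under 0.05, and limma-voom called 0 with 801 at an unadjusted p under 0.05. Both counts are a smaller share of the genes than 0.05, and the trend was fitted to these same genes, so they are no sign of an excess. With 1 library shifted in 200 genes of the real counts the edgeR test called 0% of them at a 4-fold and 0% at a 16-fold shift, so the absence of calls does not rule out differences of that size. Without replicate 2, 3 or 4 the test called 46, 2 and 11 genes, and 336 with no filter on low counts.

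The biological coefficient of variation (BCV) was 0.211 for lncRNAs and 0.230 for protein-coding genes, and in 10 bins of mean count the lncRNA value was the higher in 2. Without replicate 2 the values were 0.118 for lncRNAs and 0.0817 for protein-coding genes, so the order of the classes turned. It turned as well with no filter on low counts, at 0.246 for lncRNAs and 0.243 for protein-coding genes in all 3 libraries. Across 15624 detected genes, which are not independent replicates, Pearson's r of log2 TPM was 0.953 between replicates 2 and 3, 0.958 between 2 and 4 and 0.983 between 3 and 4. No pair of libraries agreed within sampling noise (chi-square over its degrees of freedom of 129.8, 115.5 and 11.4), so none was counted as a repeat deposit of another; separate libraries exceed that noise in any case, and these values do not measure how far the replicates differed. Among 9780 protein-coding genes, the median log2 deviation from a gene's mean over the libraries went from -0.17 for transcripts under 1000 bases to 0.36 for those over 8000 in replicate 2, from 0.14 to -0.31 in replicate 3 and from -0.0091 to -0.071 in replicate 4.

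**Figure D5:**
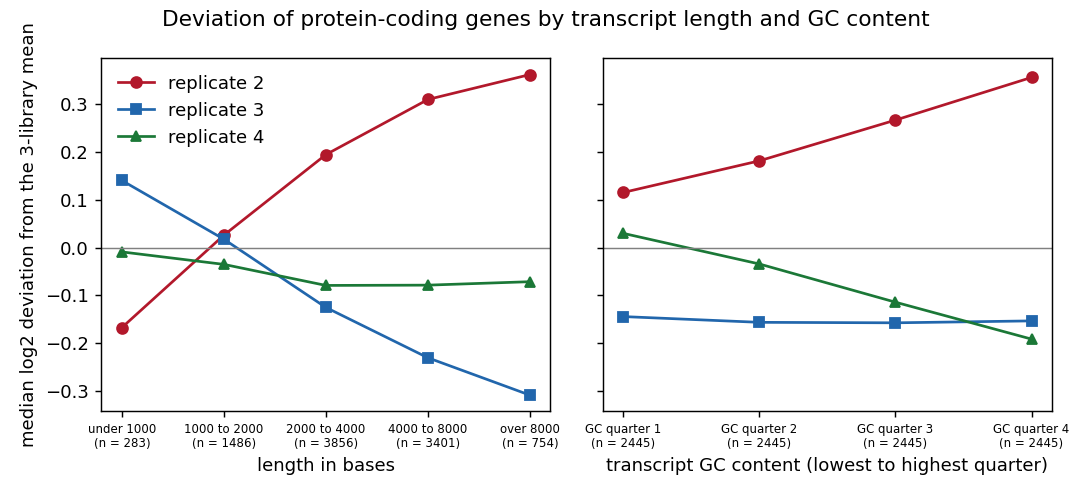
Median log2 deviation of protein-coding genes from their mean over the 3 libraries (y axis) in bins of transcript length in bases (left) and of transcript GC content (right), for replicates 2, 3 and 4. The replicate 2 line runs from -0.17 in the shortest bin to 0.36 in the longest, and the replicate 3 line from 0.14 to -0.31.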

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

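The alternatives that take gene class from the deposited type column alone, count unresolved entries as lncRNA, require lncRNAs of 200 bases or remove the length and GC trend were chosen after seeing the data. The order of lncRNA below protein-coding level held under all alternatives run, with log2 differences from -4.02 with no filter to -0.63 with class from the deposited type alone. That type column alone gave 4549 detected protein-coding and 5697 detected lncRNA genes, since it names the type of 1 transcript and not of the gene. A TPM minimum of 5 left 539 lncRNA genes, and left 6 colonocyte, 2 Paneth, 0 enteroendocrine, 0 tuft, 5 stem cell and Wnt, 1 immune, 1 stromal, 2 inflammation, 2 factor-linked lncRNA, 0 immune lncRNA, 0 imprinted lncRNA and 4 colorectal cancer lncRNA genes detected; a minimum of 0.5 gave 2 immune lncRNAs. All protein-coding genes, mitochondrial ones included, held 90.0% of TPM, and lncRNAs 2.51%. As shares of estimated counts the same classes held 95.8% (protein-coding) and 1.84% (lncRNA), and with mitochondrial genes left out of the TPM total 92.0% and 2.92%. Rescaled to nuclear protein-coding genes, 179 gene levels and 13 list medians moved up by more than 1 SD, and 263 and 11 moved by less. With the length and GC trend removed, 1 list median (inflammation or immune lncRNAs) moved by more than 1 SD and 23 did not. That removal shifts the libraries against each other and leaves a gene's mean log2 level over them as it was. A mean of list medians could thus hardly move, so the 23 say nothing about length or GC bias in the levels. With the trend removed, the deviation of the stromal list in replicate 2 fell from 0.714 to 0.117 and that of the cell junction list from 0.395 to 0.125.

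In CPM, which lack the length correction, the log2 ratio turned to -2.11 for GATA6-AS1 against GATA6 and -0.64 for HOXA11-AS against HOXA11, and kept its sign at -6.42 for HNF4A-AS1 against HNF4A, 8.62 for KCNQ1OT1 against KCNQ1, -3.16 for CDKN2B-AS1 against CDKN2B and -1.73 for LINC00261 against FOXA2. List means and CPM kept the sign of the enterocyte difference for all 10 lists; for the Paneth list they gave 1.77 and 3.06, higher in 3 of 3 libraries in both, and CPM gave 3.53 for the colonocyte list. With 1 library left out, GATA6-AS1 against GATA6 ranged from -0.20 (without replicate 3) to 0.21, KCNQ1OT1 against KCNQ1 from 2.56 (without replicate 4) to 4.15, HNF4A-AS1 against HNF4A was -2.003 without replicate 2, and the enterocyte against the Paneth list from -0.056 (without replicate 2) to 1.21. With 1 library left out, the BCV ranged from 0.0817 to 0.274 for protein-coding genes and from 0.118 to 0.248 for lncRNAs, lowest without replicate 2 in both; the lncRNA value was the higher without replicate 2 and with no filter on low counts (0.246 against 0.243), and the lncRNA value was lower still, 0.1004, as the root of the median DESeq2 gene-wise dispersion. The count of genes that varied more than the trend ranged from 2 to 46 with 1 library left out, and was 336 with no filter on low counts. The cause of these shifts was not tested beyond what the settings themselves change. Differences between classes, lists and gene pairs were taken within each library, and no pairing between groups was possible because there is 1 group. With 3 libraries the exact p cannot fall below 0.25, and with 2 not below 0.5, so no sign-flip test could pass a threshold of 0.05.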

Other observations

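The groups in these opening paragraphs, and the tests below on GC content, fragment length, library scaling, differentiation, HNF4A and transcript length, were chosen after the values were seen; the tests on library depth and on the corrected proliferation list were set before their own outcomes were seen, although the length and GC correction itself was added after the data were seen. Mucin genes were mostly below the detection minimum. None of 4 gel-forming mucins was detected, with MUC2 at 0.194 ± 0.0983 TPM and MUC5AC at 0.119 ± 0.0428 TPM (n = 3), and 2 of 8 membrane mucins were, MUC13 at 19.8 ± 17.6 TPM and MUC3A at 7.12 ± 5.52 TPM. MUC13 stood at 40.06 TPM in replicate 2 against 8.47 and 10.86 TPM in replicates 3 and 4, MUC3A at 13.5 against 4.60 and 3.32 TPM, and the membrane mucin list median at 3.3 against 0.4 and 0.579 TPM. Of 6 keratins of simple epithelia, 5 were detected, led by KRT8 at 548 ± 106 TPM, KRT18 at 357.4 ± 69.3 TPM and KRT19 at 346.2 ± 84.3 TPM. The others were low: KRT23 was at 6.91 ± 4.5 TPM and KRT20, which marks the differentiated gut epithelium, at 6.02 ± 0.518 TPM. KRT7 was at 5.49, 0.343 and 0.576 TPM in replicates 2, 3 and 4.

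Of 18 clotting and complement factors, proteins that the liver secretes into plasma, 13 were detected. Kininogen (KNG1) stood at 102.2 ± 31.4 TPM, prothrombin (F2) at 85.21 ± 21.4 TPM, complement factor B (CFB) at 67.51 ± 14.2 TPM and factor X (F10) at 62.94 ± 12.7 TPM, but factor IX (F9) was at 0.00754 ± 0.0131 TPM and plasminogen (PLG) at 0.377 ± 0.239 TPM. HOX genes, which record position along the body axis, were low: 6 of 13 posterior members were detected, led by HOXA9 at 5.06 ± 1 TPM, and 5 of 12 anterior members, led by HOXC4 at 10.84 ± 1.51 TPM. HOXD9, HOXD10, HOXD11 and HOXD13 stood at most at 0.0237 ± 0.0207 TPM. All 24 cytosolic ribosomal protein genes were detected, with medians of 3790 TPM in replicate 2, 6120 in replicate 3 and 5400 in replicate 4.

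Long protein-coding transcripts stood highest in the replicate 2 library and lowest in replicate 3, with slopes of 0.137 and -0.119 in log2 deviation per doubling of length. A GC effect alone is argued against, since the slope was 0.186 with a GC term. An error in the correction for fragment length is argued against by a slope of 0.11 among transcripts over 2000 bases, although the median gap between length and effective length was 164, 175 and 183 bases in replicates 2, 3 and 4. The replicate 2 slope was 0.136 after all libraries were thinned to the smallest total, above the bound of 0.0685 set beforehand. This argues against unequal read sampling as the source of the slope in these genes. Thinning leaves the relative levels of well-counted genes as they were. It cannot test other effects tied to library depth, which stay open, a reading adopted after the value was seen. RNA integrity and library batch were not tested, as the labels record neither, and no biological explanation was tested because the design holds 1 group.

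Proliferation genes, 1 of the 24 lists, stood higher in replicate 2, with a median log2 deviation of 0.69. Removing the length and GC trend left 0.582, outside the -0.14 to 0.14 of the central 95% of random lists. The excess over all protein-coding genes was 0.474. Neither that trend nor the scaling of the library thus accounts for all of the 0.69. Random lists hold genes drawn without regard to function, so their range makes no allowance for listed genes that move together. A less differentiated culture may be a candidate explanation and stays open: after the same correction the liver list stood at -0.30, below random lists (-0.18 to 0.18), but the enterocyte list stood at 0.0522, inside its range (-0.14 to 0.13), and the bound for this test was revised after these values were seen. Proliferation was not alone: corrected alike, the membrane mucins stood at 1.46 (4 genes) and colonocyte markers at 0.494 (10 genes) in replicate 2. Paneth markers stood at -0.603 (6 genes) and ribosomal proteins at -0.46 (24 genes) there. These values are given without a range of random lists, and the mucins include MUC17, named above among the most variable genes. Mitochondrial genes held 17.7% of TPM in replicate 2 against 10.8 and 13.8%. The difference could also lie in how the samples were handled, which the labels do not record.

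HNF4A-AS1 stood lower in replicate 2, where 45 of its 394 estimated counts fell (11.4%, exact binomial 95% interval 8.45 to 15.0%) against 40.6% of all counts; the interval covers counting error only. Transcript length is argued against: its log2 deviation of -1.53 there lay below the central 95% (-0.87 to 1.01) of 844 lncRNA entries within 25% of its 648 bases. Reads shared with HNF4A on the other strand stay open: the 193 counts that HNF4A-AS1 lacked there would, as part of the 12300 of HNF4A, account for a rise of 0.0228 on the log2 scale, too little to see against an SD of 0.248 between libraries, and this test replaced an earlier one that could not decide. A check on length and GC content together, set beforehand, was void because 650 of 2099 detected lncRNAs had a GC value, and the length test took its place. The cause of the difference is open, and no biological explanation was tested.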
